A study of Homo sapiens with 2 samples.

How the data were processed

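Gene expression was measured by RNA sequencing in 1 library of parental BEAS-2B cells and 1 library of TRPV3-overexpressing BEAS-2B cells. Per the labels, cells were grown in LHC-9 medium on plates coated with collagen and fibronectin, and RNA was purified on columns with a DNase step. How the overexpressing line was made, the library kit and the read length are not given in the sources used here. Groups were taken from the genotype label of each sample.

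The deposited values are raw counts of reads per gene, and the authors made them with featureCounts 1.5.0-p3 on the opposite-strand setting, per the file headers. Gene models came from Ensembl release 87 on GRCh38.p7, per the file headers. The same headers show no option for multi-mapping reads, for reads over several genes or for paired ends, so by default reads with several alignments or within overlapping genes were left out of the counts. STAR and DESeq2 are named, without versions, per the submitters' processing notes, but the deposited counts are not normalised. Such counting lowers the values of genes with near-identical copies, such as the metallothioneins, HLA genes, keratin KRT81, histones and ribosomal proteins with pseudogenes, and those of overlapping genes, so these are uncertain.

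The files hold 58051 annotated genes, of which 22863 had a count in either library. Symbols came from a gene name table for 56948 of the IDs, and biotypes and transcript sequences from GENCODE 29. Coordinates are those of the files. Total counts were 17450658 and 17477953, and 1 count equals 0.0584 CPM in the parental and 0.0562 CPM in the TRPV3-OE library. Libraries were scaled with TMM factors (0.982 and 1.02) from edgeR 4.0.16 in R 4.3.3, and no model was fitted, since 1 library per group leaves no spread to estimate. CPM values carry exact Poisson 95% intervals. The log2 ratio is TRPV3-OE over parental, with an exact conditional binomial (Clopper-Pearson) 95% interval. A count of 0 was set to 0.5 in ratios. Measured genes have at least 100 counts summed over both libraries. A gene was called at least 2-fold higher or lower where its ratio passed 2-fold and its interval lay wholly on that side of 1.

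The genes named were chosen by a rule set before the data were examined, as were the 37 gene lists, the thresholds and most of the other settings tried. The rule took TRPV3, the 10 highest and 10 lowest ratios among protein-coding genes with at least 500 summed counts (ranked by the interval bound nearest to 1), the 5 largest gains and 5 largest losses in CPM, and up to 4 measured members of each list with the largest absolute log2 ratio. For each list the median log2 ratio of measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins, with limits at percentiles 2.5 and 97.5. This describes the 2 libraries and is no test between conditions. Lists with fewer than 5 measured members are given as values.

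The calculation was tested on simulated data in which counts for 11435 genes were drawn with counting error alone and 200 genes carried known differences. All 25 genes set 2.5-fold higher and all 25 set 2.5-fold lower were called, 0 of 25 set 1.5-fold in either direction and 0 of 11235 unchanged genes were called, and 95.2% of intervals held the true ratio. Of 200 lists of 20 genes drawn at random from the 11435, among which were the genes with known differences, 11 fell outside the percentile limits.

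The alternatives were scaling by total counts, by DESeq2 1.42.0 size factors or by upper quartile, a prior count of 5, minimums of 1, 20 and 500 counts, limits of 1.5-fold and 4-fold, protein-coding genes alone, thinning of the deeper library, random lists unmatched or matched also on length, and means in place of medians. After the data were seen, a subtraction of the median of the 50 nearest genes and the TRP list without TRPV3 were added. Some genes that the naming rule selects are not reported here. Genes of the Y chromosome were left out of the figures and of the analysis by position. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.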

Results

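RNA was sequenced from BEAS-2B, an immortalised human bronchial epithelial cell line, and from BEAS-2B cells made to overexpress TRPV3 (TRPV3-OE), a calcium-permeable cation channel of the transient receptor potential family. There was 1 library per group, from untreated cells collected at confluence. The parental library came from cells between passage 20 and 30 and the TRPV3-OE library from cells between passage 4 and 8, so passage moved with the group. Gene counts totalled 17450658 in the parental library and 17477953 in the TRPV3-OE library, with counts on 20367 and 20766 genes. The mitochondrial genome took 3.94% of the parental counts and 3.82% of the TRPV3-OE counts. With 1 library per group no difference has a replicate check and no p-value is given. Intervals are exact 95% intervals for counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules.

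The comparison asked which transcripts differ between BEAS-2B cells and the TRPV3-overexpressing line. TRPV3 itself (ENSG00000167723, chromosome 17, 3510502 to 3557995, minus strand, GRCh38) had 26 counts in the parental library and 54077 in the TRPV3-OE library. That is 1.52 counts per 1000000 counts (CPM, 0.992 to 2.22) against 3037 CPM (3011 to 3062), a 2000-fold higher level with a log2 ratio of 10.97 (10.41 to 11.58). TRPV3 made up 0.309% of all counts in the TRPV3-OE library. Among 11466 genes with at least 100 counts summed over both libraries, 609 were at least 2-fold higher and 614 at least 2-fold lower in the TRPV3-OE library, and the remaining 89.3% lay between. The difference reached 16-fold in 21 higher and 41 lower genes. Across measured genes, log2(CPM + 1) in one library correlated with the other at r = 0.928 (Pearson), where genes are not independent replicates.

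After TRPV3, the highest ratios among protein-coding genes with at least 500 summed counts were those of IP6K3 and PPP1R16B. IP6K3, an inositol hexakisphosphate kinase, went from 23 to 802 counts (33.5-fold), and PPP1R16B, a regulatory subunit of protein phosphatase 1, from 42 to 1424 (32.6-fold). PKP1, a desmosomal plakophilin, was 29.1-fold higher, and FRMD4B, a FERM-domain scaffold protein, reached 403 CPM from 17.7 CPM (22.7-fold). PRKAA2, a catalytic subunit of AMP-activated protein kinase, was 18.0-fold higher, and CAMK2B, the beta subunit of calcium/calmodulin-dependent kinase II, 8.20-fold higher at 196 CPM. The protease inhibitor SLPI (12.8-fold), the netrin receptor UNC5D (12.4-fold), the natriuretic peptide clearance receptor NPR3 (11.5-fold) and the small GTPase RHEBL1 (10.8-fold) completed the 10 highest. The largest gains in CPM included, besides TRPV3, the ribosomal protein gene RPL5 (816 to 2137 CPM), the hair keratin gene KRT81 (335 to 1511 CPM) and the fatty acid synthase gene FASN (1768 to 2795 CPM). RPL5 lies in a part of chromosome 1 where the median log2 ratio of the 50 nearest measured genes was 0.82, against 1.39 for RPL5.

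The lowest ratio among such genes was that of VIM (ENSG00000026025), the intermediate filament vimentin, with 13736 counts in the parental library and 24 in the TRPV3-OE library, a 595-fold lower level (log2 ratio −9.22, −9.86 to −8.64). The carboxypeptidase gene CPA4 (856 and 4 counts) was 223-fold lower, and the transcription factor gene NFIX (571 and 3 counts) had a log2 ratio of −7.63 (−9.91 to −6.07). CSF3, which encodes granulocyte colony-stimulating factor, was 63.8-fold lower, the adhesion molecule gene L1CAM 63.7-fold, and CDH2, which encodes N-cadherin, 36.5-fold. THBS2 (thrombospondin 2) was 28.8-fold lower, the sialomucin gene PODXL 24.7-fold, IL1B 19.5-fold and IGFBP3, which encodes a carrier of insulin-like growth factors, 18.5-fold. By loss in CPM the first genes were ACTB (6164 to 4095 CPM), MT-ND4 (7395 to 5420 CPM), the amino acid transporter gene SLC7A5 (4217 to 2768 CPM), the fibronectin gene FN1 (1501 to 143 CPM) and HSP90AA1 (3211 to 1860 CPM).

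**Figure D1:**
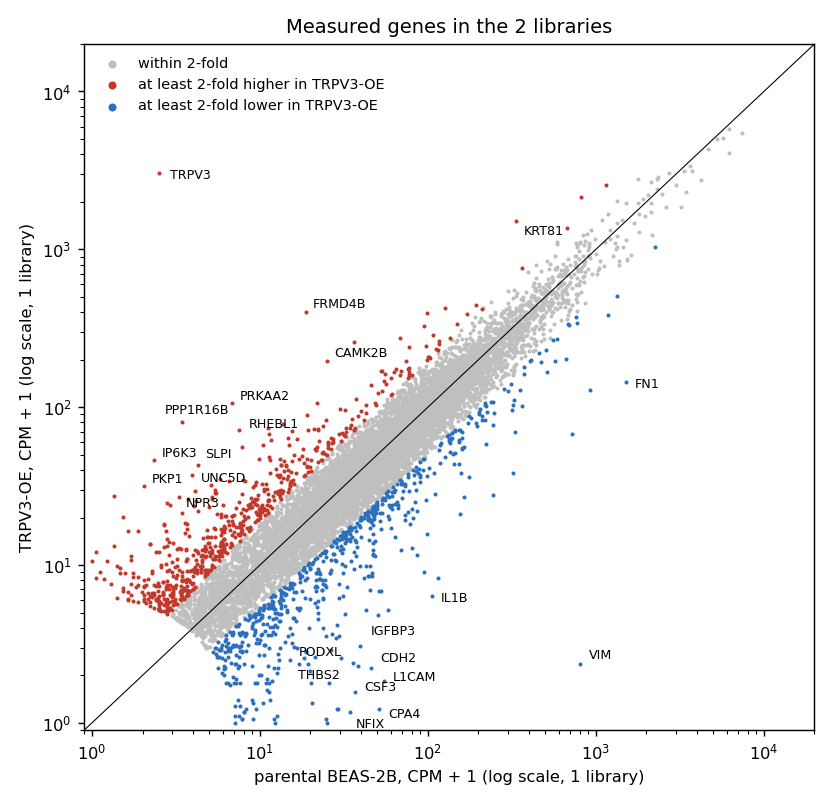
Each point is 1 of the measured genes outside the Y chromosome, at its CPM + 1 in the parental library (x axis, log scale) and in the TRPV3-OE library (y axis, log scale), with 1 library per axis. Red points are genes at least 2-fold higher and blue points genes at least 2-fold lower in TRPV3-OE, the line marks equal levels, TRPV3 stands alone at 3037 CPM against 1.52, and VIM lies far to the right at 802 CPM against 1.35.

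Genes typical of mesenchymal cells were lower in the TRPV3-OE library. Of 12 measured members of the mesenchymal list, 9 were at least 2-fold lower and 0 higher, with a median log2 ratio of −1.82, at percentile 0 of 10000 random lists matched on expression. Besides VIM and CDH2, the list held ZEB1, a repressor of epithelial genes, with 116 parental counts and 1 TRPV3-OE count (log2 ratio −6.91, −12.23 to −4.41), and FN1 (10.5-fold lower). Epithelial junction genes went the other way, with 6 of 23 at least 2-fold higher, 0 lower and a median of 0.63 (percentile 100). PKP1 led them, followed by the tight junction genes TJP3 (10.4-fold), CLDN4 (4.58-fold) and CLDN7 (3.22-fold). E-cadherin (CDH1), named here after its value was seen, had a log2 ratio of −0.09.

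The extracellular matrix list had 10 of 19 members lower and 0 higher (median −1.07, percentile 0). Among them the collagen genes COL12A1 (479 and 4 counts, 125-fold), COL5A2 (5.82-fold) and COL4A1 (4.50-fold, basement membrane) were lower in TRPV3-OE. Matrix proteases and their inhibitors followed, with 5 of 11 lower and 0 higher (median −0.94, percentile 0), including the gelatinase gene MMP2 (124 and 4 counts, 32.2-fold) and MMP14 (2.22-fold). In the TGF-beta response list 4 of 19 members were lower and 3 higher (median −0.48, percentile 0.05, but −0.27 at percentile 3.23 with no count minimum). INHBA, an activin subunit gene, was 9.28-fold lower and THBS1 3.09-fold lower, while the ligand gene BMP4 was 3.08-fold higher. Integrins did not stand apart as a list (2 of 14 higher, 2 lower, median −0.25, percentile 8.02, or 2.10 after subtraction of neighbouring genes), with ITGA6 3.32-fold lower and ITGB2, the leukocyte integrin beta chain, 4.89-fold higher. Targets of the density-sensing factor YAP had 3 of 14 members lower and 0 higher (median −0.21, percentile 11.4, but a mean of −0.81 at percentile 0.18), among them ANKRD1 with 111 and 2 counts (log2 ratio −5.85, −8.91 to −3.96).

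Airway basal cell markers were lower as a list, with 7 of 13 at least 2-fold lower, 0 higher and a median of −1.03 (percentile 0). COL17A1, a hemidesmosome collagen, was 4.19-fold lower, DLK2 2.79-fold and the caveolin gene CAV1 2.64-fold. Secretory and goblet cell markers split, with SLPI (12.8-fold) and WFDC2 (3.29-fold) higher and the mucin gene MUC4 (31.3-fold) and the goblet cell factor SPDEF (2.36-fold) lower. Their median over 5 measured members was 1.05 (percentile 99.6, 3 higher and 2 lower), but their mean was 0.05 (percentile 59.5), and the median was 0.50 (percentile 95.2) after subtraction of neighbouring genes. Ciliated cell markers had 0 of 6 higher and 1 lower, the tubulin gene TUBA1A at 4.05-fold, with a median of 0.38 (percentile 85.1). The squamous differentiation list, included because TRPV3 is best known from skin keratinocytes, had a median of 0.01 over 7 measured members (percentile 58.0), with KRT80 4.00-fold higher and S100A8 3.71-fold lower. Few markers of other cell types were measured. COL1A1 and FBLN1 of the fibroblast list had log2 ratios of −0.58 and 0.56, the endothelial cadherin gene CDH5 was 7.96-fold lower and the alveolar marker AGER had a log2 ratio of −0.05. CD14, the only measured member of the immune cell list, went from 72 to 460 counts.

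Inflammatory genes were lower in the TRPV3-OE library, with 8 of 18 cytokine, chemokine and NF-kappaB genes at least 2-fold lower, 0 higher and a median of −0.75 (percentile 0.01). With a minimum of 500 counts the median of the 11 members left was −0.35 (percentile 2.90), inside the limits. Alongside CSF3, the interleukin 1 genes IL1B (104 to 5.33 CPM) and IL1A (113 to 7.24 CPM, 15.6-fold) and the neutrophil chemokine gene CXCL1 (13.4-fold) were lower. CXCL1, CXCL2, CXCL3 and NFKB1 of this list lie on chromosome 4. The 50 genes nearest to NFKB1 had a median log2 ratio of −0.735, against −1.42 for NFKB1. After subtraction of local medians CXCL1, CXCL2 and CXCL3 had log2 ratios of −3.20, −1.98 and −3.12. The senescence list, which shares IL1A, IL1B and CXCL1 with the inflammatory list, had 6 of 14 members lower and 1 higher (median −0.67, percentile 0). Interferon response genes had 6 of 15 members lower and 0 higher (median −0.62, percentile 0.12), including IRF7, a transcription factor of that response (4.18-fold, log2 ratio −2.06, with a median of −0.68 over its 50 nearest genes), IFI6 (3.41-fold) and IFITM3 (2.18-fold). In the antigen presentation list 6 of 14 members were lower and 0 higher (median −0.95, percentile 0). Its immunoproteasome genes PSMB9 (4.32-fold) and PSMB8 (2.91-fold) and HLA-E (2.63-fold) were lower. Of these 14 genes 10 lie on chromosome 6, where the median log2 ratio of the 50 genes nearest to HLA-E was −0.44, and reads that align to several HLA genes are not in the counts.

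In the TRP channel list 4 of 10 measured members were at least 2-fold higher and 0 lower (median 0.55, percentile 99.3). Besides TRPV3 these were TRPV4 (21 and 223 counts, 10.2-fold), TRPV1 (30 and 86 counts, 2.76-fold) and the endolysosomal channel gene MCOLN3 (2.24-fold, log2 ratio 1.17, with a median of 0.59 over its 50 nearest genes). TRPV4 shares 1 stretch of 20 bases with TRPV3 and TRPV1 shares 2. Without TRPV3 the median of the list was 0.50 (percentile 97.7), and with no count minimum the full list fell inside the limits (percentile 96.8). Calcium-handling genes had 3 of 28 lower and 0 higher (median −0.17, percentile 11.2), namely the sodium/calcium exchanger gene SLC8A1 (10.9-fold), the inositol trisphosphate receptor gene ITPR2 (3.70-fold) and the annexin gene ANXA1 (2.27-fold). Of 6 calcineurin and NFAT targets, EGR3 was 7.63-fold higher (14 and 111 counts) and TNFAIP3 2.86-fold lower (median 0.39, percentile 88.7). Immediate early genes divided as well, with ATF3 (2.24-fold) and KLF4 (2.15-fold) higher and FOS (2.54-fold) and FOSL1 (2.47-fold) lower among 16 (median −0.10, percentile 30.9).

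Most lists of stress and growth signalling did not stand apart. The unfolded protein response had 1 of 20 members higher, ATF3, and 1 lower, HERPUD1 at 2.17-fold (median 0.09, percentile 85.3). Heat shock genes had 0 higher and 0 lower among 15 (median −0.12, percentile 26.1), with HSP90AA1 at a log2 ratio of −0.79. EGFR ligands and ERK feedback genes had 2 of 19 lower, the ligand genes HBEGF (366 and 127 counts) and AREG (2.72-fold), and a median of 0.12 (percentile 93.4, or 98.3 after subtraction of neighbouring genes). The 50 genes nearest to AREG on chromosome 4 had a median log2 ratio of −0.68, against −1.44 for AREG. The p53 targets had GDF15 2.44-fold higher and the DNA repair gene DDB2 3.07-fold lower among 21 (median 0.15, percentile 94.2). NRF2 targets had 1 of 18 higher, GCLM of glutathione synthesis (2.05-fold), and 2 lower, AKR1B10 (8.87-fold) and the cystine transporter gene SLC7A11 (2.21-fold). The 50 nearest genes had a median log2 ratio of 0.85 around GCLM, itself at 1.03, and of −0.69 around SLC7A11, itself at −1.14. Their median of −0.29 (percentile 2.45) kept its side of the limit in 5 of 11 alternative settings. In the WNT and NOTCH list 5 of 19 members were higher and 5 lower (median −0.21, percentile 8.23, but a mean of −0.48 at percentile 1.99), with WNT10A 3.14-fold higher, the NOTCH ligand gene DLL1 11.9-fold lower, and WNT7A at 105 and 2 counts (log2 ratio −5.77, −8.84 to −3.88).

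Proliferation genes differed by small amounts. Among 30 mitosis genes 0 were higher and 1 lower, cyclin A2 (CCNA2, 2.25-fold), with a median of −0.26 (percentile 1.10) but a mean of −0.18 inside the limits (percentile 7.61). CCNA2 had a log2 ratio of −1.17 beside a median of −0.60 over its 50 nearest genes on chromosome 4. None of the 33 DNA replication genes passed 2-fold in either direction (median −0.08, percentile 31.0). Hypoxia and glycolysis genes had 5 of 25 higher and 0 lower (median 0.09, percentile 89.9), among them ANGPTL4 (4.07-fold), the oxygen sensor gene EGLN3 (3.13-fold) and the carbonic anhydrase gene CA9 (2.24-fold). Of 22 sterol genes 1 was higher and 0 were lower (median 0.03, percentile 79.4). Xenobiotic metabolism genes had CYP1A1 (2.17-fold) and CYP2S1 (2.46-fold) higher and NNMT (2.54-fold) lower among 10 (median 0.16, percentile 88.4). Metallothioneins and the zinc exporter gene SLC30A1 (3.18-fold) had 3 of 5 higher and 0 lower (median 1.196, percentile 100). MT1F was 4.58-fold and MT1X 2.29-fold higher while MT2A, the most abundant, had a log2 ratio of −0.80, and reads that align to several of these near-identical genes are not in the counts. Ribosomal protein genes had a median of 0.13 over 38 members (percentile 99.6, but 96.1 among unmatched random lists and 96.5 for the mean), with RPL5 alone past 2-fold (2.62-fold) and RPS24 at a log2 ratio of 0.91. The list of mitochondrially encoded genes had 0 of 13 members higher and 0 lower (median −0.09, percentile 41.1). The histone genes H1-2 and H2AC6 were 6.81-fold and 8.72-fold lower.

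**Figure D2:**
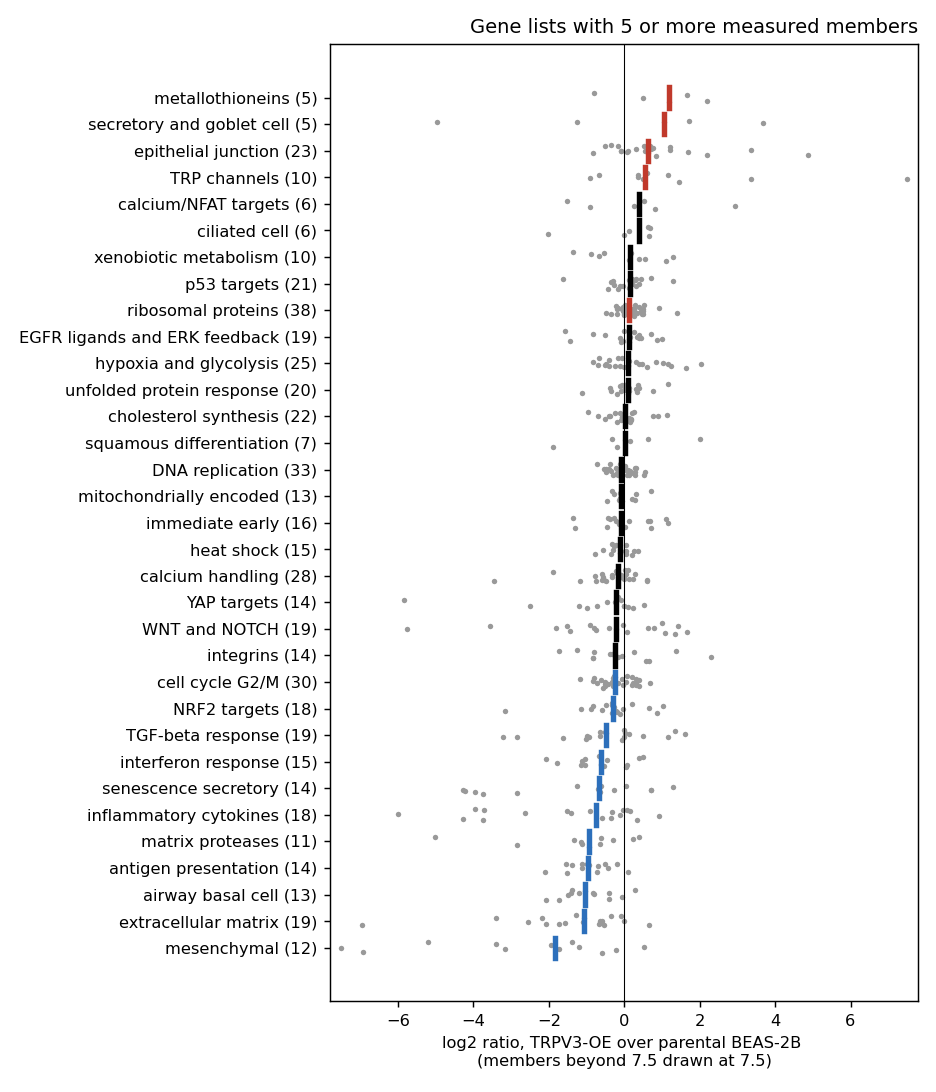
Each grey point is the log2 ratio (TRPV3-OE over parental) of 1 measured member of a gene list, and each bar is the list's median, for the 33 lists with at least 5 measured members (number in brackets, 1 library per group). Medians past the upper percentile limit of matched random lists are red (5 lists), those past the lower limit are blue (11 lists), members beyond the axis are drawn at its ends, and the mesenchymal list lies lowest at −1.82 and the metallothioneins highest at 1.196.

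Of 33 lists with at least 5 measured members 16 lay outside the percentile limits, where 1.65 would by chance if genes varied independently. The random lists draw genes independently, whereas listed genes can vary together or lie side by side. The value of 1.65 is therefore no expected number for lists like these. Of the 534 measured genes in lists, 23 belong to 2 or more lists. In 8 of those 16 lists the members were spread so widely that an order-statistic interval of the median held 0, namely TRP channels (−0.66 to 3.35), TGF-beta response (−0.98 to 0.12), matrix proteases (−2.85 to 0.23), secretory cells (−4.97 to 3.68), mitosis (−0.43 to 0.07), senescence (−3.96 to 0.72), interferon response (−1.12 to 0.04) and metallothioneins (−0.80 to 2.20). For a gene with 100 counts split evenly the interval of the log2 ratio is 1.19 wide, so small differences in such genes were not detectable at this depth. Like the called genes with a local value given above other than IRF7, ATF3, HERPUD1, IFITM3, ANXA1 and DDB2 lay below 2-fold once the median of their 50 nearest genes was subtracted. So did members counted in the lists but not named there, among them ISG15 (−1.05 to −0.84) and RIGI (−1.04 to −0.80) of the interferon list. In the antigen presentation list HLA-C (−1.125 to −0.63) and NLRC5 (−1.11 to −0.83) did so, while CD74 went from −0.98 to −1.01. The counts of members in the lists are those before this subtraction.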

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

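The subtraction of the median of the 50 nearest genes and the TRP list without TRPV3 (median 0.50) were tests chosen after the results were seen, and the others were planned. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The TRPV3 ratio stayed within its interval in every alternative run for it. The numbers of genes at least 2-fold higher and genes at least 2-fold lower were 609 and 614, and became 1347 and 1121 with no minimum beyond 1 count, 1094 and 942 with a minimum of 20, 245 and 323 with a minimum of 500, 1455 and 1627 at 1.5-fold, and 151 and 159 at 4-fold, as fewer or more genes qualify by construction. Scaling by total counts gave 669 and 547, and upper quartile 679 and 541. No scaling moved the median of measured genes by more than 0.0582. Of 592 values of named genes under other scalings and the prior count of 5 (subtraction of neighbours not included) 534 stayed within their interval, 58 moved and 0 reversed. Of 404 list values 373 held, 30 moved and 1 reversed. The list immune cell, CD14 alone in the main setting (2.62), was 2.67 by total counts, 2.66 by DESeq2 factors, 2.68 by upper quartile, 2.54 with a prior count of 5 and 2.51 after subtraction of neighbours, and reversed to −0.056 without a minimum, where it holds 5 genes. The prior count of 5 gave NRF2 targets −0.29 (percentile 2.76) and histones −2.70. Without a minimum, medians were TRP channels 0.50 (percentile 96.8), TGF-beta response −0.27 (3.23), fibroblast markers −1.06 (2.0), NRF2 targets −0.24 (3.71) and histones −1.98. A minimum of 20 gave fibroblast markers −1.24 over 4 genes and NRF2 targets −0.24 (3.72), and a minimum of 500 gave inflammatory cytokines −0.35 (2.90) over 11 genes. Against unmatched random lists the percentiles passed a limit for alveolar and endothelial markers (−1.52, 1.39), NRF2 targets (−0.29, 2.68) and ribosomal proteins (0.13, 96.1). Means were 0.05 for secretory cells, −0.18 for G2/M (7.61), −0.34 for NRF2 targets (6.16), −0.81 for YAP targets (0.18), −0.48 for WNT and NOTCH (1.99) and 0.17 for ribosomal proteins (96.5). Subtraction of neighbours gave EGFR ligands 0.17 (98.3), integrins −0.25 (2.10), secretory cells 0.50 (95.2), NRF2 targets −0.10 (20.8), YAP targets −0.29 (0.49) and histones −2.31. Apart from the changes of member genes by construction, the cause was not tested. The mesenchymal, extracellular matrix, protease, basal cell, senescence, interferon, antigen presentation, epithelial junction and metallothionein lists kept their side of the limits in all 11 alternatives.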

Other observations

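The gene families below, the windows along chromosomes, the fibroblast tests, the chance-order test and the TRPV2 test were chosen after the results were seen, while the GC and length tests, the test without strongly changed genes, the neighbour subtraction for the mesenchymal list and the test of sequence shared by TRPV3 and TRPV4 were written down before their values were computed, though medians by chromosome had been seen. Homeobox clusters differed in opposite directions. Of 6 measured HOXB genes 5 were at least 2-fold lower in TRPV3-OE, including HOXB9 (110 and 7 counts, 16.3-fold) and HOXB2 (192 and 22 counts, 9.07-fold), and 0 were higher. Of 5 measured HOXA genes 2 were higher, HOXA10 (76 and 489 counts, 6.19-fold) and HOXA11 (38 and 178 counts, 4.51-fold), and 0 lower. These genes set position along the body axis, and none of the HOXC or HOXD genes reached 100 counts.

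Of 12 measured keratins, KRT81 and KRT80 were higher and KRT15 (2.29-fold) and KRT17 (2.05-fold), both basal cell keratins, were lower, while the basal keratin KRT5 had a log2 ratio of −0.40 and the simple-epithelium keratins KRT8, KRT18, KRT19 and KRT7 had 0.38, 0.35, 0.45 and −0.25. The regulatory subunit gene PRKAR2B of cyclic AMP-dependent kinase went from 33 to 410 counts, while PRKAR2A, PRKAR1B and PRKAR1A had log2 ratios of 0.05, −0.06 and −0.58. Among subunits of calcium/calmodulin-dependent kinase II, CAMK2B was higher (log2 ratio 3.04) and CAMK2D and CAMK2G had ratios of −0.56 and 0.28. Of 120 measured long intergenic RNAs 15 were higher and 17 lower, from LINC01451 (12 and 184 counts, 14.7-fold higher) to LINC01224 (139 and 6 counts, 24.1-fold lower), with UCA1 11.1-fold lower.

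Neighbouring genes shifted together along chromosomes. Across 218 windows of 50 measured genes the SD of the window medians was 0.285, while 1000 shuffled gene orders reached 0.0919 at most. That excludes a fully random gene order and no more, since shuffling also separates gene families and overlapping genes. The SD stayed at 0.276 after correction for GC content and transcript length and at 0.244 without genes past 2-fold. Medians lay at or below −0.4 in 20 windows and at or above 0.4 in 10, many side by side. They were −0.82 to −0.57 in every window of chromosome 4 from 57.0 to 183.4 Mb. On chromosome 11 from 0.2 to 47.4 Mb they were −0.68 to −0.67, and on X from 0.3 to 100.6 Mb −0.68 to −0.575. On chromosome 1 from 53.9 to 149.9 Mb they were 0.405 to 0.88, and on chromosome 20 from 0.3 to 25.1 Mb 0.42 and 0.62. On chromosome 4 between 82.9 and 105.3 Mb all 50 genes were below 0 (median −0.82), the first window of chromosome 6 (0.3 to 14.1 Mb) had a median of −0.84, and on chromosome 1 between 92.0 and 108.9 Mb 48 of 50 were above 0 (median 0.88). Subtracting the median of the 50 nearest genes left 573 genes at least 2-fold higher and 431 genes at least 2-fold lower, from 609 and 614. The antigen presentation list went from −0.95 to −0.74 when local medians were subtracted, its interval then running from −1.24 to 0.06. A difference in DNA copy number between the cultures is a candidate explanation that may be checked on DNA, and it was not tested here.

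The mesenchymal list, with VIM, ZEB1 and CDH2 lowest, had a median of −1.77 after the GC and length correction and −1.81 after subtraction of local medians, both at percentile 0 of random lists, which argues against either trend as the whole cause. The 12 members are spread widely, and the intervals of these medians reach −0.38 and −0.35, so the size of the list's median is uncertain. The summed fibroblast markers (1720 and 2215 counts, log2 ratio 0.31) decide nothing, since COL1A1 and FBLN1 carry them, and the other 11 markers were lower in TRPV3-OE (65 and 17 counts). Those 65 counts have an upper limit of 82.8, or 0.603% of the 13736 parental counts of VIM, and COL1A2, COL3A1, LUM and DCN, abundant in fibroblasts, had 1, 0, 0 and 5, which argues against fibroblasts in the parental culture as the source of VIM. With 1 library per group, an effect of TRPV3 itself cannot be told apart from passage (20 to 30 against 4 to 8). Nor can it be told apart from selection while the line was made, or from any other difference between the cultures.

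TRPV4 and TRPV1 were higher beside TRPV3, and reads of the abundant TRPV3 transcript counted for these paralogs are one technical explanation. The test written beforehand asked whether TRPV3 shares any stretch of 20 bases with TRPV4. It found 1, out of 9821 in TRPV3 transcripts, the outcome that explanation needs. That outcome cannot decide the question, since a gene without a gain can share a stretch too. A second test, added because of that outcome, used TRPV2, which also shares 1 stretch but had 2 counts in each library, an upper counting limit of 7.22 against the 202 counts TRPV4 gained (0.374% of the TRPV3 counts). TRPV1, which shares 2 stretches, gained fewer counts than TRPV4. The first test thus decides nothing, and the second goes against the explanation but rests on a single gene with a bound set afterwards. The paralog explanation therefore stays open, because read length and the inserted sequence are not known, as does a higher expression of TRPV4 and TRPV1, which the design does not separate from passage.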
